A study of Homo sapiens with 18 samples.

How the data were processed

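Affymetrix gene expression arrays were made from SK-OV-3 cells, a human ovarian carcinoma line, with 18 arrays in 8 groups. Per the labels' protocols, growing cells were kept for 48 h with recombinant hepatocyte growth factor (HGF) at 50 ng/mL or in control medium, and fresh medium with cisplatin, with or without HGF, was then added. The cisplatin concentration is printed in the labels as 10 with a garbled unit, which was read as micromolar. RNA was taken at 0, 6, 12 and 24 h. The 0 h arrays were read as taken before cisplatin, which the labels do not state in so many words. The 2 time courses, called TR5 and TR7 in the labels, were done independently per the series text. Each group has 1 array of each experiment, except that the 0 h groups have 2 arrays of TR5 and 1 of TR7. No group received fresh medium without cisplatin, so the change over time combines cisplatin, time in culture and the change of medium. The labels of arrays 6 and 8 carry the mark bis, which they do not explain. All labels were kept as deposited.

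The deposited values are log2 expression values per probe set, and per the submitters' processing notes they were made with affy and RMA, whose versions are not given in the sources used here. Background correction, normalization settings and array dates are not given in the sources used here either. The values of the 22215 probe sets lie between 3.387 and 14.84 on the log2 scale. The array medians lie between 6.898 and 7.053 and the standard deviations (SD) of the arrays between 1.799 and 2.039. No 2 arrays hold identical values. Of the probe sets, 19065 are listed with 1 gene symbol, 1043 with several and 2107 with none, and 19053 symbols were updated by Entrez ID through a RefSeq gene table of assembly GRCh38.p14, from which no coordinates or lengths were used. A gene was represented by its probe set with the highest mean over all arrays among those with 1 symbol, which gave 11963 genes.

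Differences were tested with limma 3.58.1 under R 4.3.3 (lmFit and eBayes without trend or robust settings) in one fit over all 18 arrays, with the 8 groups and the experiment as an additive block, which left 9 residual degrees of freedom. The block rests on the labels, which name the experiment of each array. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05 with no fold threshold. Changes are log2 differences with the standard error (SE) of the fit. There were 13 comparisons: HGF against no HGF at 0, 6, 12 and 24 h and averaged over 6, 12 and 24 h, the change from 0 h to each later time without and with HGF, the HGF difference after cisplatin minus that at 0 h, and an F test over the 3 interaction terms. The comparisons, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined.

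The genes named are, for 4 main comparisons (HGF at 0 h, HGF averaged over 6, 12 and 24 h, 24 h against 0 h without HGF, and the difference between HGF differences), the 10 highest and 10 lowest log2 changes among called genes with the same sign in TR5 and in TR7, and for the other comparisons the 3 highest and 3 lowest. Where no gene was called, the 5 genes with the lowest p are given as not passing. Up to 4 members of each gene list, MET, HGF, CDKN1A and the protein phosphatase 2A (PP2A) subunits were named in any case.

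The 25 gene lists cover p53 targets, DNA repair, DNA damage checkpoint, G1/S and DNA replication, G2/M and mitosis, histones, MAPK/ERK immediate-early and feedback, stress kinases, invasive growth, the BCL2 family, death receptors and caspases, PP2A subunits, unfolded protein and integrated stress response, NF-kB and cytokines, interferon response, platinum transport and metallothioneins, epithelial junctions and keratins, mesenchymal genes, sterol and fatty acid synthesis, glycolysis and hypoxia, heat shock, ribosomal proteins, and markers of fibroblasts, leukocytes and endothelium. Each was tested against all other genes with camera at a preset correlation of 0.01, adjusted over the lists within a comparison. The camera test with the correlation estimated from the residuals and fry were alternatives. Values of fry are not given list by list. Members were also counted with p adjusted over the list alone.

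The tests were first run on simulated data with 200 of 11963 genes changed. For HGF averaged over 6, 12 and 24 h, 34.5% of genes changed by 0.5 on the log2 scale, 88.0% of those changed by 1 and 99.5% of those changed by 2 were called. For HGF at 0 h the shares were 0%, 72.5% and 97.5%, for 24 h against 0 h without HGF 0.5%, 64.0% and 93.0%, and for the difference between HGF differences 0%, 62.5% and 93.5%. The camera test found a list planted in the simulated data, and 2 of 100 random lists passed 0.05. The simulated noise was independent between genes and between arrays, with the same spread of a gene on every array. The check therefore does not give the error rate for lists whose members vary together. Nor do its shares of called genes hold where real arrays differ in spread or are not independent.

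The alternatives were a fit without the experiment, the 2 TR5 arrays of each 0 h group averaged first, quantile normalization of the deposited values, the mean of all probe sets of a gene, genes below the median signal left out, eBayes with trend and robust settings, only the compared groups in the fit, a fold threshold of 1 on the log2 scale, and each array left out in turn. For the HGF average, a block for each pair of arrays of one experiment and time, and fits within TR5 and within TR7, were added. One alternative, chosen after seeing the data, left out both HGF arrays of TR7 at 0 h and 6 h. Probe sets with several symbols or none were left out of all comparisons and appear only in the closing section. Gene length was not examined, and no lengths were taken from the gene table. Figures were drawn with matplotlib 3.10.9.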

Results

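Gene expression was measured on 18 arrays of SK-OV-3 ovarian carcinoma cells that had been kept for 48 h with or without HGF, the ligand of the receptor tyrosine kinase MET, and then given the platinum drug cisplatin. At 0 h there were 3 arrays with HGF and 3 without, and at 6, 12 and 24 h there were 2 arrays with HGF and 2 without. Of the 18 arrays, 10 came from the experiment TR5 and 8 from TR7. Arrays carry the numbers of their labels, which add the mark bis to the numbers of arrays 6 and 8 without saying what it means. Values are log2 expression levels, a difference of 1 standing for a 2-fold change. The number of arrays limits the precision of every value. P-values measure the spread between these arrays, and the labels do not state whether the paired TR5 arrays of the 0 h groups came from separate cultures. The TR5 pair with HGF had the highest correlation of any 2 arrays (r = 0.995), and that without HGF had r = 0.992. If they did not, the spread is understated. With each pair averaged first, HGF averaged over 6, 12 and 24 h gave 727 called genes instead of 1162. The question set by the design was which transcripts HGF alters before and during exposure to cisplatin.

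The largest source of variation was time. The first principal component held 55.0% of the variance. A time scale was set from the arrays without HGF, with 0 for the mean of the 0 h arrays and 1 for that of the 24 h arrays, over 4462 genes of which 1967 rose and 2495 fell. On this scale the 0 h arrays without HGF lay at -0.00794, -0.0691 and 0.0771, the 6 h arrays at 0.386 and 0.262, the 12 h arrays at 0.772 and 0.801, and the 24 h arrays at 0.926 and 1.07. With HGF, the 0 h arrays of TR5 lay at 0.163 and 0.108, whereas array 6, the 0 h array of TR7, lay at 0.407. At 6 h with HGF, array 9 of TR5 lay at 0.808 and array 10 of TR7 at 0.252. Thus in TR7 the HGF array labelled 6 h lay before the one labelled 0 h. The level of GDF15, a secreted stress marker, was 8.34 on array 6 and 6.85 on array 10. At 12 h with HGF the positions were 0.834 and 0.599, and at 24 h 1.03 and 0.931. All labels were kept as deposited, and counts without arrays 6 and 10, a choice made after seeing the data, are given beside the results that these arrays enter.

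**Figure D1:**
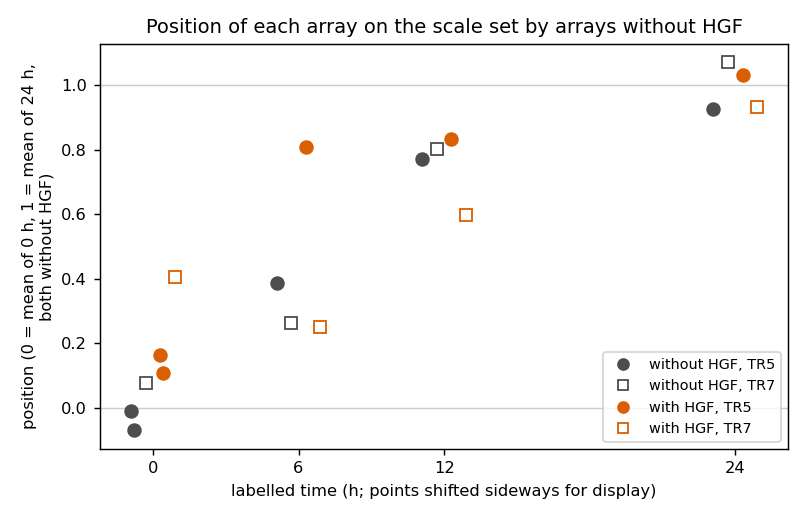
Position of each of the 18 arrays on the time scale (vertical axis, no unit, 0 for the mean of the 0 h arrays and 1 for that of the 24 h arrays without HGF) against hours of cisplatin (horizontal axis), with TR5 and TR7 and arrays with and without HGF marked. In TR7 the HGF array labelled 0 h lies at 0.407 and the one labelled 6 h at 0.252.

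After 48 h of HGF and before cisplatin, ZNF112, a zinc finger gene, was lower by a log2 difference of -1.54 (SE 0.202, 3 arrays with and 3 without HGF, limma adjusted p = 0.0479), from a level of 6.69 ± 0.188 to 5.15 ± 0.46 (SD, n = 3 each). TERF1, which encodes a telomere-binding protein, was lower by -0.85 (SE 0.116, limma adjusted p = 0.0479), from 10.04 ± 0.15 to 9.19 ± 0.144 (SD, n = 3 each). These were the 2 genes called. Among the lists, G1/S and DNA replication genes (27 of 34 below 0) and the unfolded protein and integrated stress response genes (21 of 30 below 0) were lower than other genes with camera adjusted p = 0.0102 each, and both had adjusted p = 0.868 with an estimated correlation. DNA repair genes were lower with adjusted p = 0.0319, and adjusted p = 0.868 with an estimated correlation. In each of these 3 lists 0 members passed over all genes and 0 passed adjusted over the list alone. Without the experiment in the fit the G1/S and DNA repair lists had adjusted p = 0.128 and 0.0705, and with genes below the median signal left out the stress response and DNA repair lists had 0.125 and 0.139. Without adjustment, 1378 genes had p under 0.05, and across genes the differences within TR5 and within TR7 correlated with r = 0.641, genes not being independent replicates. Neither gene stayed called in every setting. The count was 0 without both arrays out of the order of time and 0 without array 1, 2, 3, 4, 5, 6, 11, 12, 13 or 14, and it was 1 without array 15 or 16, 4 without array 7 or 8 and 10 without array 9 or 10. The count was also 0 with the TR5 arrays of each 0 h group averaged and 0 without the experiment in the fit. With only the compared groups in the fit it was 1152, 330 higher and 822 lower, these 2 genes included.

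Over 6, 12 and 24 h of cisplatin together, ASNS, which makes asparagine, was lower with HGF by a log2 difference of -2.55 (5.87-fold, SE 0.349, 6 arrays with and 6 without HGF, limma adjusted p = 0.0018). MAT2A, which makes S-adenosylmethionine, was lower by -2.41 (SE 0.317, adjusted p = 0.0017), and PSAT1 of serine synthesis by -2.08 (SE 0.321, adjusted p = 0.00311). DUSP6, a phosphatase that ERK signalling induces, was lower by -2.15 (SE 0.38, adjusted p = 0.0056). The replication genes CDC6 (-1.81, SE 0.28, adjusted p = 0.00313) and DTL (-1.70, SE 0.25, adjusted p = 0.00259) were lower too. EIF5 of translation initiation was lower by -1.92 (SE 0.233), LCMT2 by -1.76 (SE 0.177), PURA by -2.10 (SE 0.282) and the RNA methylation gene WTAP by -1.69 (SE 0.215), with adjusted p between 0.000692 and 0.0017. At 24 h the level of ASNS was 11.17 ± 0.306 without and 8.37 ± 0.825 with HGF, and that of DUSP6 8.68 ± 0.462 without and 6.13 ± 1.57 with HGF (SD, n = 2 each).

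Higher with HGF over the same times were DPYD, which breaks down pyrimidines (2.06, SE 0.487, limma adjusted p = 0.0213), KRT14, a keratin (1.86, 3.64-fold, SE 0.333, adjusted p = 0.00595), and FTO, an RNA demethylase (1.80, SE 0.34, adjusted p = 0.00765). The next were DBP (1.36), MSR1 (1.34), INSIG1 of sterol feedback (1.22), GBE1 of glycogen synthesis (1.22), RBPMS (1.16), PCCA (1.16) and SEPTIN9 (1.12), with SE from 0.187 to 0.339 and adjusted p from 0.00409 to 0.0418. DPYD stood at 0.83 in TR5 and 3.28 in TR7, and the size of its difference is uncertain because its level at 24 h without HGF was low (4.53 ± 0.0878, SD, n = 2). In all, 1162 genes were called, 330 higher and 832 lower with HGF, and 148 of them differed at least 2-fold, 16 higher and 132 lower. The median difference of all genes was 0.0691. Of the 20 named genes, 14 stayed called whichever array was left out, and 5 stayed called in every other setting. Without array 8 the other 6, DBP, DPYD, GBE1, INSIG1, PCCA and RBPMS, lost the call. With a replicate block by pair of experiment and time 539 genes were called, 45 higher and 494 lower, and DPYD, GBE1, INSIG1, PCCA and RBPMS lost the call. Without the experiment in the fit CDC6, DTL, GBE1, INSIG1 and MSR1 lost it. Within TR5 alone 9 of the 20 lost it, and within TR7 alone 14 did, CDC6 and DTL among these 14. Other probe sets of LCMT2, PURA and WTAP did not all have the same sign. The differences within TR5 and within TR7 correlated across genes with r = 0.44. Fewer genes were called within TR5 alone (201, 193 of them lower) and within TR7 alone (16, 14 of them lower). Without arrays 6 and 10 there were 1979, of which 1055 were also called with them. The count moved by over 1.5 times without array 8 (418), 10 (1891), 11 (612), 12 (677), 13 (750), 14 (567), 15 (628) or 18 (704).

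**Figure D2:**
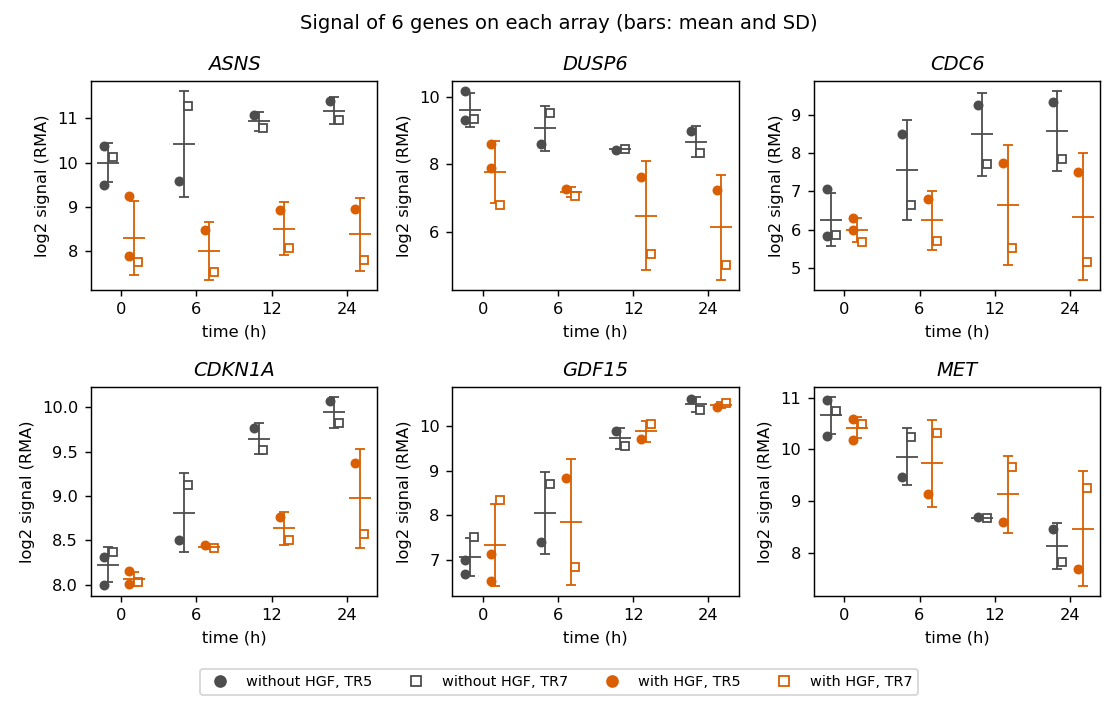
Log2 expression (vertical axes) of ASNS, DUSP6, CDC6, CDKN1A, GDF15 and MET against hours of cisplatin (horizontal axes), with 1 point per array, circles for TR5, open squares for TR7, grey for arrays without and orange for arrays with HGF, and bars for the group mean and SD. ASNS lies near 8.37 with and 11.17 without HGF at 24 h, whereas GDF15 reaches 10.46 with and 10.48 without.

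Of the fixed lists, G1/S and DNA replication genes stood lowest with HGF over 6, 12 and 24 h: 17 of 34 measured members were lower and 0 higher, 21 lower and 1 higher adjusted over the list alone. Besides CDC6 these included MCM10 (-1.03, SE 0.206), PCNA (-0.96) and MCM5, parts of the replication machinery. Against other genes the list had camera adjusted p = 1.49e-12, and adjusted p = 0.201 with an estimated correlation. In the unfolded protein and integrated stress response list 10 of 30 members were lower and 1, PDIA4 (0.61), was higher, 15 lower and 2 higher adjusted over the list alone (camera adjusted p = 1.71e-05). SLC7A11, the cystine transporter (-1.65, SE 0.253), and PHGDH of serine synthesis (-1.46, SE 0.235) were among them. Of 31 MAPK/ERK immediate-early and feedback genes 7 were lower and 0 higher, 9 lower and 1 higher adjusted over the list alone (camera adjusted p = 7.63e-05), with ATF3 at -1.08 (SE 0.286), DUSP4 at -0.92 (SE 0.251) and HBEGF at -0.81 (SE 0.146). DNA repair genes had 5 of 35 lower, 6 adjusted over the list alone (camera adjusted p = 0.00366): XPA (-0.85, SE 0.129), BARD1 (-0.74), RAD51C (-0.61), FANCF (-0.56) and MSH6 (-0.40). The checkpoint list had 3 of 19 lower, 3 adjusted over the list alone (camera adjusted p = 0.0346): TIPIN (-0.94, SE 0.171), CDC25A (-0.54) and RAD1 (-0.42). The heat shock list had 3 of 16 lower, HSPA4L (-0.57), BAG3 (-0.34) and DNAJA1, and 4 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.031). Each of these 5 lists had adjusted p = 0.201 with an estimated correlation. After quantile normalization the checkpoint and heat shock lists had camera adjusted p = 0.0582 each. With genes below the median signal left out, the DNA repair, checkpoint and heat shock lists had 0.133, 0.305 and 0.239, and without the experiment in the fit the checkpoint list had 0.0543.

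G2/M and mitosis genes were higher than other genes with HGF, 30 of 35 lying above 0 (camera adjusted p = 0.0346, adjusted p = 0.653 with an estimated correlation), and KIF20A, a mitotic kinesin, was the member called (0.60, SE 0.154), with 0 adjusted over the list alone. Without arrays 6 and 10 the list had camera adjusted p = 0.185. Endothelial markers, which stand for another cell type, had 10 of 10 members above 0 at a median of 0.178 (camera adjusted p = 0.031, adjusted p = 0.201 with an estimated correlation), with CLDN5 called (0.31, SE 0.0886) and 2 adjusted over the list alone, and with genes below the median signal left out the list had camera adjusted p = 0.305. Leukocyte markers had 16 of 16 above 0 at a median of 0.137 (camera adjusted p = 0.0561), with CD74 called (0.45) and 2 adjusted over the list alone. These medians lay above that of all genes, 0.0691. With genes below the median signal left out, the median of the genes kept was -0.0333. The HGF difference thus varied with signal level, for which the marker lists were not matched. The SD of an array averaged 1.914 ± 0.054 with HGF and 1.972 ± 0.0607 without (SD, n = 9 each), a difference of -0.0587 (two-sided exact permutation test over 48620 splits, p = 0.0468). With arrays exchanged only within an experiment and time, a test added after the values were seen, the exact permutation p was 0.0547 over 768 splits, and without the TR7 pair of 6 h, which holds array 10, the difference was -0.0375 (exact permutation p = 0.109). Within TR5 it was -0.0667 (exact permutation p = 0.0417 over 48 exchanges within a time) and within TR7 -0.0486 (0.75 over 16). In TR7 it came to 0.0112 without that pair, and there the SD was higher with HGF at 12 h (1.954 against 1.887) and at 24 h (1.889 against 1.859).

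The other lists were not set apart from other genes by HGF over 6, 12 and 24 h on all arrays and genes with the experiment in the fit, although single members were called. Of 23 p53 targets GADD45A (-0.88), CDKN1A (-0.79) and TP53I3 (-0.62) were lower and CCNG1 (0.50) higher, 3 and 1 adjusted over the list alone (camera adjusted p = 0.0526). Among 17 BCL2 family genes PMAIP1 (-1.23), BNIP3 (-1.13) and BCL2L13 (-0.57) were lower, 4 adjusted over the list alone (adjusted p = 0.0938). The death receptor and caspase list held CASP8 (-0.93, SE 0.148), CYCS (-0.73) and FADD (-0.59), all lower, and 3 adjusted over the list alone (25 measured, adjusted p = 0.0526). Stress kinase genes DUSP1 (0.98), GADD45B (0.97) and MAP3K5 (0.64) were higher and GADD45A and MAP2K4 (-0.70) lower, 3 and 2 adjusted over the list alone (28 measured, adjusted p = 0.698). In the invasive growth list the urokinase receptor gene PLAUR (0.58) was higher and the protease gene MMP7 (-0.47) lower, 1 and 1 adjusted over the list alone (34 measured, adjusted p = 0.111). Of the mesenchymal list SNAI1 (0.51) and AXL (0.51) were higher and TGFBR2 (-0.86) lower, 2 and 1 adjusted over the list alone (31 measured, adjusted p = 0.359), and of the epithelial list PERP (-0.66) and LSR (-0.49) were lower, 2 adjusted over the list alone (26 measured, adjusted p = 0.539).

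Interferon response genes IFIT5 (-1.07), SAMD9 (-0.67) and HERC6 (-0.40) were lower with HGF over the same times, 3 adjusted over the list alone (27 measured, camera adjusted p = 0.0902). Of the platinum transport and metallothionein list HMOX1 (0.73), the drug exporter gene ABCC1 (0.60) and GSTM1 (0.42) were higher and SLC31A2 (-0.36) lower, 3 and 1 adjusted over the list alone (28 measured, adjusted p = 0.884). INSIG1, ACACA and MVK of the sterol and fatty acid list were higher, 4 higher and 1 lower adjusted over the list alone (20 measured, adjusted p = 0.108). In the glycolysis list SLC2A1 was higher and BNIP3 and ENO2 (-0.81) were lower, 1 and 2 adjusted over the list alone (26 measured, adjusted p = 0.111). The histone gene H2AZ1 was lower (-0.44), 1 adjusted over the list alone (11 measured, adjusted p = 0.0926). By limma, 0 of 23 NF-kB genes, 0 of 23 ribosomal protein genes and 0 of 12 fibroblast markers were called, and 0 adjusted over each list alone (camera adjusted p = 0.834, 0.359 and 0.894). With quantile normalization the p53, histone, invasive growth and sterol lists had camera adjusted p = 0.0497, 0.0241, 0.0487 and 0.0241, in the same directions, and adjusted p = 0.176 each with an estimated correlation. Without the experiment in the fit the p53 and death receptor lists were lower with camera adjusted p = 0.0443 each (0.262 and 0.238 with an estimated correlation), and with genes below the median signal left out the sterol list was higher with 0.0345 (0.538 with an estimated correlation).

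At single times after cisplatin, the HGF difference at 6 h included ZFPL1 (1.62, SE 0.262), TCF7L1 (0.90) and MRPL2 (0.78), which were higher, and the chaperone regulator BAG2 (-1.82, SE 0.273), the Wnt receptor FZD1 (-1.77, SE 0.288) and the splicing factor SRSF1 (-1.66, SE 0.323), which were lower (n = 2 each, limma adjusted p from 0.0306 to 0.0471). CRAT (0.76) and SPSB3 (0.66), named after their values were seen, were the other genes called higher. Other probe sets of FZD1 did not have its sign. Of 62 genes called at 6 h, 5 were higher and 57 lower, and after quantile normalization 18 of 75 were higher. The values within TR5 and within TR7 correlated across genes with r = 0.107, and without arrays 6 and 10 there were 822 genes called, 415 higher and 407 lower. Leaving out 1 array gave from 0 (without array 4, 5 or 8) to 926 (without array 9), and the count stayed within 1.5 times when array 6, 15 or 16 was left out. The 6 genes named first lost the call without array 1, 4, 5 or 8, without the experiment in the fit, with the TR5 arrays of each 0 h group averaged and with only the compared groups in the fit. BAG2 lost it in no other setting tried, FZD1 also without array 3 and with the probe sets of a gene averaged, and the rest in more. At 12 h limma called 0 genes, with 728 at an unadjusted p under 0.05. The lowest p-values were those of BAG5 (-0.91), FEM1B (-1.70), WDR73 (-0.76), TMEM185B (-1.32) and TPST1 (0.67), which did not pass (adjusted p = 0.328 each). The count at 12 h was 1 without array 6, 7 or 8 and 1 without arrays 6 and 10.

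At 24 h HGF raised DPYD by 3.81 (SE 0.843, limma adjusted p = 0.0498), SUCLG2 of the citric acid cycle by 2.37 (SE 0.404, adjusted p = 0.0192) and adenosine kinase, ADK, by 2.16 (SE 0.324, adjusted p = 0.0169), against cisplatin alone at the same time. MAT2A (-3.31, SE 0.55, adjusted p = 0.018), PURA (-3.09, SE 0.489, adjusted p = 0.0169) and ASNS (-2.80, SE 0.604, adjusted p = 0.0455) were lower, with 2 arrays against 2. DPYD stood at 1.65 in TR5 and 5.96 in TR7, at levels of 8.34 ± 2.96 with and 4.53 ± 0.0878 without HGF (SD, n = 2 each), so low without HGF that the size of its rise and its rank are uncertain. Together 166 genes were called, 30 higher and 136 lower, and 455 without arrays 6 and 10. The correlation of TR5 with TR7 across genes was r = 0.251. Leaving out 1 array gave from 0 (without array 18) to 805 (without array 17), and the count stayed within 1.5 times when array 6, 7 or 8 was left out. DPYD kept the call without array 9, 10 or 17 and lost it when any other array was left out, after quantile normalization and with the probe sets of a gene averaged. ASNS lost it without array 1, 2, 3, 4, 6, 11, 12, 13 or 14, and all 6 lost it without array 15, 16 or 18. All 6 also lost it with the TR5 arrays of each 0 h group averaged or with only the compared groups in the fit, and without the experiment in the fit ADK alone kept it.

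By camera 6 lists were called for HGF at 6 h, 7 at 12 h and 9 at 24 h. G1/S genes were lower with HGF at 6 h (camera adjusted p = 1.23e-05), at 12 h, where 34 of 34 lay below 0 (adjusted p = 8.39e-14), and at 24 h (adjusted p = 4.89e-10), where CDC6 and GINS4 were called lower and E2F2 higher (9 lower and 1 higher adjusted over the list alone). With an estimated correlation their adjusted p was 0.409, 0.365 and 0.257. G2/M genes were higher at 12 h, 35 of 35 lying above 0 (adjusted p = 5.65e-10, adjusted p = 0.375 with an estimated correlation). MAPK/ERK genes were lower at 24 h (adjusted p = 2.92e-07, adjusted p = 0.257 with an estimated correlation), with JUN at -1.63 (SE 0.293) and HBEGF at -1.40 (SE 0.253) called and 6 lower adjusted over the list alone, and lower at 12 h (adjusted p = 0.0264, adjusted p = 0.474 with an estimated correlation). The stress response list was lower at 6 h (adjusted p = 0.00103), 12 h (0.00234) and 24 h (1.63e-05, 10 lower and 2 higher adjusted over the list alone), with adjusted p = 0.409, 0.474 and 0.257 with an estimated correlation. At 6 h the heat shock and ribosomal protein lists were lower (adjusted p = 0.00103 each, 0.268 and 0.409 with an estimated correlation). DNA repair genes were lower and endothelial markers higher at 6 h (adjusted p = 0.0226 each, 0.409 each with an estimated correlation) and at 24 h (adjusted p = 0.0132 and 0.0251, 0.257 each with an estimated correlation). The checkpoint and the death receptor lists were lower at 24 h (adjusted p = 0.0251 each, 0.257 each with an estimated correlation). At the same time leukocyte markers were higher (adjusted p = 0.0492, 0.386 with an estimated correlation) and interferon response genes lower (adjusted p = 0.0498, 0.354 with an estimated correlation). At 12 h the mesenchymal (adjusted p = 0.00701), invasive growth (0.00783) and sterol (0.00512) lists lay above other genes, with adjusted p = 0.249, 0.249 and 0.365 with an estimated correlation. After quantile normalization the ribosomal protein and endothelial lists at 6 h (adjusted p = 0.074 and 0.105) and leukocyte markers at 24 h (0.103) were not called. Without arrays 6 and 10 the stress response, ribosomal protein and endothelial lists at 6 h were not called (adjusted p = 0.177, 0.611 and 0.108). With genes below the median signal left out, G1/S genes were the list still called at 6 h, the MAPK/ERK and invasive growth lists at 12 h had adjusted p = 0.131 and 0.11, and of the 9 lists at 24 h the G1/S, MAPK/ERK and stress response lists stayed called. None of the list calls of the HGF comparisons held with an estimated correlation. The alternative fry could differ from this: of the calls of the DNA repair list it lost 3, where the estimated correlation lost 4.

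Over 24 h of cisplatin without HGF, ID1, an inhibitor of basic helix-loop-helix factors, rose by 5.49 (SE 1.56, 2 arrays at 24 h and 3 at 0 h, limma adjusted p = 0.0186). UBE2S, a ubiquitin-conjugating enzyme of mitosis, rose by 4.45 (SE 1.2, adjusted p = 0.0144), MRPS12 of the mitochondrial ribosome by 4.42 (SE 0.977, adjusted p = 0.00528) and the stress-induced factor ATF3 by 3.46 (SE 0.453, adjusted p = 0.000279). PLPP2 (3.81), CRIP2 (3.74), CYBA (3.72), AP2M1 (3.58), MIF and SCAND1 completed the 10 with the largest rise. DPYD fell by 6.75 (SE 0.772, adjusted p = 0.00012), from 11.15 ± 0.276 (SD, n = 3) to 4.53 ± 0.0878 (SD, n = 2). This last level lay below the lower quartile of every array (5.65 to 5.89), and signal over background was not analysed. The size of a change from or to such a level, and a rank by it, is therefore uncertain for any gene, and no fold is given where a gene reaches one on an array compared. The receptor phosphatase gene PTPRK fell by 5.42 (SE 0.76, adjusted p = 0.000403). FTO (-4.26, SE 0.539, adjusted p = 0.000227) and the calcineurin gene PPP3CA (-4.18, SE 0.53) fell as well. Further falls were those of NLGN4X (-4.13, SE 0.373, adjusted p = 3.89e-05), the focal adhesion kinase gene PTK2 (-3.94, SE 0.645) and the adhesion gene CADM1 (-3.91, SE 0.366, adjusted p = 4.71e-05). SMYD3 (-4.19), OSBPL10 (-4.15) and TMEM135 were also among the 10 lowest, and other probe sets of OSBPL10 did not have its sign.

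In this comparison 3932 genes were called, 1775 higher and 2157 lower at 24 h, and 1803 of them changed at least 2-fold, 529 upward and 1274 downward. The median of all genes was 0.103. The changes within TR5 and within TR7 correlated across genes with r = 0.804. Of the 20 named genes, 13 stayed called whichever array was left out. ID1, UBE2S, AP2M1, MIF and PLPP2 lost the call without array 15 or without array 16, and CRIP2 and SCAND1 without array 16. ID1 also lost it without array 1 or 2, and AP2M1 without array 2, and ID1, AP2M1 and MIF lost it with the TR5 arrays of each 0 h group averaged. The count was 1288 without array 16, the TR7 array of this group, and 4732 without arrays 6 and 10, of which 3904 were also called with them.

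Mitotic genes were the list that fell most clearly by 24 h without HGF: 16 of 35 G2/M members were lower and 1, AURKB (1.30), higher, 17 and 1 adjusted over the list alone (camera adjusted p = 0.0012, adjusted p = 0.792 with an estimated correlation). Among them were ASPM (-2.12, SE 0.348), DLGAP5 (-1.94, SE 0.571) and the motor genes KIF11 (-1.84, SE 0.384) and KIF14 (-1.69, SE 0.19). When genes below the median signal were left out, this list had camera adjusted p = 0.12. NF-kB and cytokine genes rose, with 9 of 23 higher and 1, CXCL1 (-1.11), lower, the same counts adjusted over the list alone (camera adjusted p = 0.0138, adjusted p = 0.689 with an estimated correlation). CXCL8, a neutrophil chemokine, rose by 3.19 (SE 0.669) and TNFAIP2 by 1.67 (SE 0.293). G1/S genes had 10 of 34 higher and 1, POLA1 (-1.68), lower, 12 and 1 adjusted over the list alone (camera adjusted p = 0.0848), with CDC6 at 2.57 (SE 0.445), CDT1 at 1.87 and MCM2 at 1.58, and after quantile normalization their adjusted p was 0.018 (adjusted p = 0.626 with an estimated correlation).

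Damage response genes changed in both directions over 24 h without HGF and were not set apart as lists. Of 23 p53 targets 7 were higher and 4 lower, 9 and 4 adjusted over the list alone (camera adjusted p = 0.547): GDF15 rose by 3.38 (SE 0.578), GADD45A by 1.83 (SE 0.375), CDKN1A by 1.73 (SE 0.233) and the death effector BAX by 1.44 (SE 0.412), and CYFIP2 fell by 1.95 (SE 0.254). DNA repair genes had 6 higher and 8 lower of 35, 7 and 12 adjusted over the list alone (adjusted p = 0.301), among them NBN (-1.57), RAD50 (-1.52) and the translesion polymerase gene REV3L (-1.42). Of 19 checkpoint genes 2 were higher and 5 lower, 2 and 5 adjusted over the list alone (adjusted p = 0.547), with the kinase gene ATR at -2.04 (SE 0.459), TOPBP1 at -1.33, MDC1 at -1.32 and H2AX at 1.95. The stress response list had 7 of 30 higher and 1, SEL1L (-1.92), lower, 7 and 1 adjusted over the list alone (adjusted p = 0.301), with SLC3A2 at 3.03 (SE 0.494) and PHGDH at 2.09. Interferon response genes had 9 of 27 higher and 7 lower, 9 and 7 adjusted over the list alone (adjusted p = 0.547), with IRF7 at 2.90 (SE 0.335) and ISG15 at 2.54. Of 25 death receptor and caspase genes TNFSF10 (-2.71, SE 0.45), FAS (-0.85) and CFLAR (-0.79) were lower and TNFRSF10D (1.06) and CASP2 (0.38) higher, 3 and 1 adjusted over the list alone (adjusted p = 0.798). CFLAR had the opposite sign, 0.10, when the probe sets of a gene were averaged.

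Adhesion, junction and metabolic lists likewise split over 24 h without HGF. In the invasive growth list 4 of 34 were higher and 7 lower, 6 and 7 adjusted over the list alone (camera adjusted p = 0.798), with MMP10 at -1.83 (SE 0.238), the integrin gene ITGA6 at -1.71 and CD44 at -1.60. Mesenchymal genes had 5 of 31 higher and 10 lower, the same counts adjusted over the list alone (adjusted p = 0.17), with TGFBR2 at -2.31 (SE 0.275), ZEB1 at -2.19, CDH2 at -1.61 and TGFB1 at 3.15. Epithelial genes had 6 of 26 higher and 2 lower, the same counts adjusted over the list alone (adjusted p = 0.265), with KRT8 at 2.85 and TJP1 at -1.75. Of the sterol and fatty acid list 4 of 20 were higher and 5 lower, 5 and 7 adjusted over the list alone (adjusted p = 0.762), with ACACA among the lower, HMGCS1 at -1.50 (SE 0.4) and FASN at 2.02. Markers of other cell types moved singly: the stromal gene LUM fell by 1.68, CD3D was higher by 0.48, and EGFL7 (1.15) and VWF (0.49) were higher. Fibroblast, leukocyte and endothelial markers had camera adjusted p = 0.301 each, with 1, 0 and 1 members called adjusted over the list alone. By limma, 0 of 23 ribosomal protein genes were called (camera adjusted p = 0.894).

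**Figure D3:**
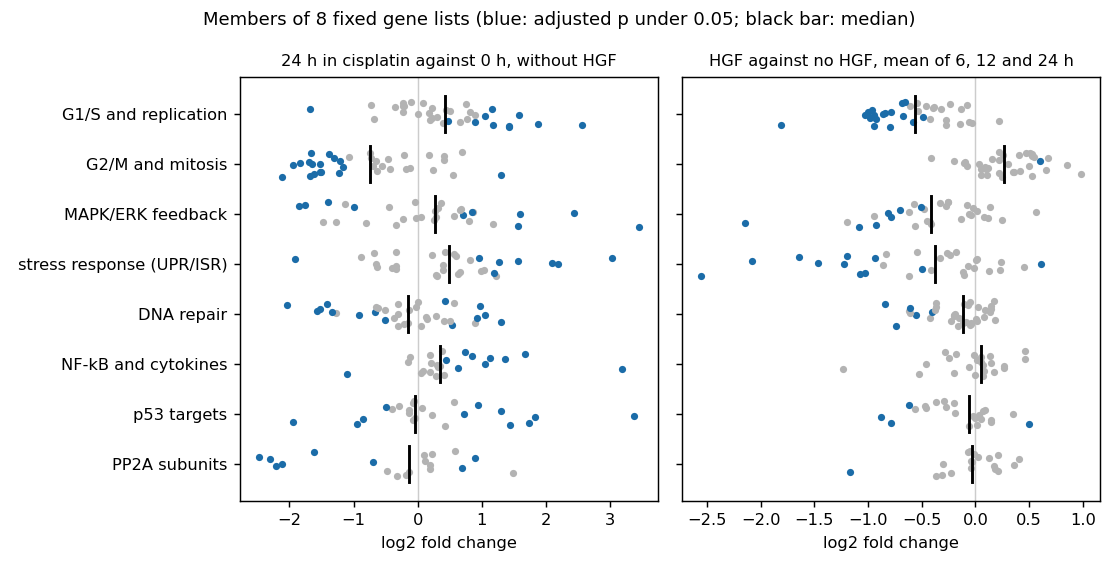
Log2 difference (horizontal axis) of each measured member of 8 fixed gene lists, for 24 h against 0 h without HGF and for HGF averaged over 6, 12 and 24 h, with 1 point per gene, blue where the adjusted p is under 0.05, and a bar for the list's median. Of the G1/S list 17 members were lower with HGF and 10 were higher at 24 h without it.

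At 6 h without HGF the 3 lowest were NR3C2, the mineralocorticoid receptor gene (-2.58, SE 0.228, 2 arrays against 3, limma adjusted p = 0.000811), HDAC4 (-2.22, SE 0.234, adjusted p = 0.00295) and ATXN1 (-2.09, SE 0.314, adjusted p = 0.0305). All 18 genes called at 6 h were lower, and 81 were called without arrays 6 and 10. ATXN1 lost the call without array 1, 2, 3, 4, 8, 15, 16, 17 or 18, and all 3 lost it without array 7. The count ran from 0 (without array 7) to 49 (without array 9 or 10) and stayed within 1.5 times when array 5, 13 or 14 was left out. G2/M genes were lower at 6 h (camera adjusted p = 6.09e-10, adjusted p = 0.498 with an estimated correlation), G1/S genes higher (adjusted p = 0.000306, adjusted p = 0.838 with an estimated correlation) and the platinum transport and metallothionein genes higher (adjusted p = 0.00118, adjusted p = 0.0506 with an estimated correlation). At 12 h UBE2S (3.75, SE 1.2), MRPS12 (3.59, SE 0.977) and AP2M1 (3.11, SE 0.994) were highest and PTPRK (-4.04, SE 0.76), ZMIZ1 (-3.82, SE 0.481) and NLGN4X (-3.68, SE 0.373) lowest, with limma adjusted p from 0.000182 to 0.0474. At this time 2202 genes were called, 720 higher and 1482 lower, and 3376 without arrays 6 and 10. Without array 1 the count was 1165, without array 2 it was 1196, without array 11 it was 827 and without array 12 it was 358. UBE2S and AP2M1 kept the call at 12 h without array 3, 6, 9 or 10 and lost it when any other array was left out. MRPS12 lost it without array 1, 2, 11 or 12 and PTPRK without array 12. With the TR5 arrays of each 0 h group averaged all but the 3 lowest lost it, and UBE2S lost it after quantile normalization. Of the G2/M list 17 were lower at 12 h (adjusted p = 8.24e-08, adjusted p = 0.75 with an estimated correlation), and of the G1/S list 10 were higher and 1 lower (adjusted p = 0.0203, adjusted p = 0.786 with an estimated correlation). The G1/S list was not called without the experiment in the fit (adjusted p = 0.194 at 6 h and 0.366 at 12 h) or with genes below the median signal left out (0.104 and 0.167).

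With HGF, NR3C2 was the gene called at 6 h against 0 h, lower by -1.95 (SE 0.228, 2 arrays against 3, limma adjusted p = 0.018). By 12 h with HGF the differentiation inhibitor ID2 (1.23, SE 0.248), POMZP3 (0.77) and PRKAA1 (0.73) were higher and ZMIZ1 (-2.84, SE 0.481), HMGA2 (-2.75, SE 0.406) and ATXN1 (-2.52, SE 0.314) lower. ABHD4 (0.71) and SPSB3 (0.58), named after their values were seen, were the other genes called higher at that time. By 24 h MRPS12 (3.32, SE 0.977), CRIP2 and GDF15, which reached 10.46 ± 0.0665 (SD, n = 2) from 7.34 ± 0.925 (SD, n = 3), had risen most. NEK7 (-3.41, SE 0.545), ZMIZ1 (-3.37, SE 0.481) and WDFY3 (-3.35, SE 0.398) had fallen most. The count was 1 gene at 6 h, 196 at 12 h (5 higher and 191 lower) and 3813 at 24 h (1921 higher and 1892 lower). Of the 1292 that changed at least 2-fold by 24 h, 188 were higher and 1104 lower, and the balance also moved with genes below the median signal left out (608 higher and 1378 lower). Without arrays 6 and 10 it was 1487 at 6 h (977 higher and 510 lower), 1478 at 12 h (776 higher and 702 lower) and 4410 at 24 h. At 6 h the values of TR5 and TR7 correlated across genes with r = -0.424, and the count was 319 without array 9, 781 without array 10, 3 without array 15 or 16 and 0 without array 3, 5, 6, 7, 8, 11 or 12. At 12 h it was 0 without array 13, 35 without array 5, 43 without array 4, 81 without array 14, 113 without array 1, 524 without array 6 and 701 without array 9 or 10. At 24 h it was 2358 without array 4, 2082 without array 5, 2129 without array 17 (833 higher and 1296 lower) and 1764 without array 18 (573 higher and 1191 lower). With the TR5 arrays of each 0 h group averaged it was 1762, 699 higher and 1063 lower. At that time MRPS12 lost the call without array 4, 5, 17 or 18 and CRIP2 without array 5 or 18, and both lost it with the TR5 arrays of each 0 h group averaged. At 12 h HMGA2 and ATXN1 lost the call without array 13, ZMIZ1 without array 4, 5 or 13, and ID2 without array 1, 4, 5, 13 or 14. POMZP3 lost it without these or array 11 or 12, and PRKAA1 without array 1, 2, 3, 4, 5, 7, 8, 13 or 14. With only the compared groups in the fit all 6 lost it, and with the TR5 arrays of each 0 h group averaged, where 17 genes were called, all but ATXN1 did. ID2, PRKAA1 and ZMIZ1 lost it without the experiment in the fit, ID2, POMZP3 and PRKAA1 after quantile normalization, and ID2 and PRKAA1 with the probe sets of a gene averaged. G2/M genes were lower at 6 h (camera adjusted p = 3.82e-05), 12 h (adjusted p = 0.00844) and 24 h (adjusted p = 0.0261, 6 lower and 0 higher), with adjusted p = 0.769, 0.712 and 0.773 with an estimated correlation. At 12 h and 24 h this list was not called without arrays 6 and 10 (adjusted p = 0.429 and 0.268) or with genes below the median signal left out (0.052 and 0.373), nor at 24 h after quantile normalization (0.141). Ribosomal protein genes were lower at 6 h (adjusted p = 8.91e-05, adjusted p = 0.74 with an estimated correlation) and had the opposite sign without arrays 6 and 10 (adjusted p = 0.918).

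The changes over 24 h with and without HGF share no arrays. Of the 3932 genes called without HGF and 3813 called with it, 2384 were called in both, 944 higher in both (285 for independent lists) and 1439 lower in both (341.1 for independent lists). Across all genes the changes correlated with r = 0.868. ANO10, a scramblase family gene named after its values were seen, was the gene called in opposite directions, at -0.43 without (SE 0.132, limma adjusted p = 0.0251) and 0.42 with HGF (adjusted p = 0.0306). At 12 h, 189 of the 196 genes called with HGF were also called without it (r = 0.887 across genes). The HGF differences at 0 h and those averaged over 6, 12 and 24 h, which share no arrays either, correlated with r = 0.621, and 1083 of the 1162 genes called after cisplatin had the same sign at 0 h. All these comparisons come from the same 2 experiments and one fit, so such agreement is not independent replication. The SD of the arrays with HGF minus that without was -0.0715 in TR5 and -0.0631 in TR7 at 0 h. Its part in the shared signs was not tested. Without arrays 6 and 10, 3155 genes were called both with and without HGF at 24 h (r = 0.883), 1473 higher and 1682 lower, and 0 in opposite directions. At 12 h 1336 of the 1478 genes called with HGF were also called without it (r = 0.868), and 1713 of the 1979 genes called for HGF after cisplatin had the same sign at 0 h (r = 0.587).

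MET, the receptor gene, fell over 24 h without HGF (-2.60, SE 0.406, limma adjusted p = 0.000754), from 10.66 ± 0.361 (SD, n = 3) to 8.14 ± 0.446 (SD, n = 2), and with HGF (-2.03, SE 0.406, adjusted p = 0.0044). HGF did not alter MET detectably at 0 h (-0.24) or over 6, 12 and 24 h (0.22, SE 0.256, adjusted p = 0.587). The HGF gene itself was higher at 24 h without HGF by 0.42 (SE 0.138, adjusted p = 0.0337). CDKN1A, the cell cycle inhibitor p21, rose over 24 h by 1.73 without (SE 0.233, adjusted p = 0.000315) and by 0.92 with HGF (SE 0.233, adjusted p = 0.0126), and lay lower with HGF over 6, 12 and 24 h by -0.79 (SE 0.147, adjusted p = 0.00711). The difference of its HGF difference after cisplatin from that at 0 h was -0.63 and did not pass (adjusted p = 1).

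Of the 19 PP2A subunit genes measured, PPP2R1B, a scaffold subunit, was lower with HGF over 6, 12 and 24 h by -1.17 (SE 0.156, limma adjusted p = 0.0017) and was the 1 called, also adjusted over the list alone (camera adjusted p = 0.439). At 24 h its level was 8.52 ± 0.204 without and 6.83 ± 0.75 with HGF (SD, n = 2 each, limma adjusted p = 0.0169). This family was taken up by the study itself, so its counts are not independent evidence. Over 24 h without HGF the regulatory subunit genes PPP2R5E (-2.47, SE 0.618), PPP2R5C (-2.31, SE 0.403), PPP2R3A (-2.21, SE 0.352), PPP2R3C (-2.12, SE 0.351), STRN3 (-1.62) and PPP2R5A (-0.70) fell, and PPP2R5D (0.89) and PPP2R2D (0.70) rose, 7 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.301). Over 24 h with HGF, PPP2R5E (-2.07), STRN3 (-1.63), PPP2R3C (-1.34), PPP2R3A (-1.33), PPP2R5C (-1.33), PPP2R1B (-1.28), PPP2CB (-0.46) and PPP2R5A fell and PPP2R5B (0.34) rose, 9 lower and 2 higher adjusted over the list alone (adjusted p = 0.182). With the probe sets of a gene averaged, PPP2CB had the opposite sign (0.17).

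Whether the HGF difference after cisplatin departed from that at 0 h was tested directly. FARS2, a mitochondrial tRNA synthetase gene (0.81, SE 0.132, limma adjusted p = 0.512), HDAC4 (1.20), LPP, TGFB1I1 (0.71) and TEAD1 (1.01) had the lowest p-values and did not pass. Limma called 0 genes, with 391 at an unadjusted p under 0.05, and 0 without arrays 6 and 10, and the count was 1 without array 16 or 17. In the F test over the 3 interaction terms limma called 0 genes, with 559 at an unadjusted p under 0.05 and the lowest p for TM9SF2, TMEM45A, PHKB, GALNT10 and FARS2 (adjusted p = 0.723). Without both arrays the F test called 15 genes, without array 9 it called 47, without array 16 it called 1 and without array 17 it called 86. As lists, G1/S genes had a median of -0.362 (camera adjusted p = 2.12e-07), MAPK/ERK genes -0.285 (adjusted p = 0.000168) and G2/M genes 0.375 (adjusted p = 0.000463), with adjusted p = 0.403, 0.403 and 0.575 with an estimated correlation. In these lists 0 members passed over all genes by limma.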

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

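In this part, 6 tests were chosen only after their result was seen: the exchange of arrays 6 and 10, their order after quantile normalization, the share of lower calls without these arrays, the splits within pairs, the splits of the difference between HGF differences, and the use of the estimated correlation, itself fixed before the data were examined, to test correlated noise.

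In TR7 the HGF array labelled 6 h lay before the one labelled 0 h on the time scale, by a difference of -0.155. The narrow spread of values on array 10 is argued against as the whole cause, since after quantile normalization, which makes the spread equal, array 10 still lay before array 6, at 0.164 against 0.38, a difference of -0.216. An exchange of both labels may explain the order: array 6 at 0.407 lay well above the TR5 0 h HGF arrays (0.163 and 0.108), and array 10 at 0.252 lay within 0.1 of them. That margin was narrow, and array 10 also lay beside the TR7 6 h array without HGF (0.262). Array 9 of TR5 lay ahead of both 6 h arrays without HGF, so the order does not settle the labels. Over all probe sets array 10 correlated most with array 5, a TR5 0 h HGF array (r = 0.970). It correlated less with the 6 h arrays without HGF (0.948 and 0.946) and with array 9 (0.922), which goes with an exchange. Within TR7, however, array 10 correlated about equally with the 0 h and 6 h arrays without HGF (0.947 and 0.946). The highest correlation of array 10 was also the lowest such value of any array, and its SD (1.799) was the lowest. Whether array 10 is of poor quality was not tested. Array 6 correlated most with array 14 of 12 h (0.988). Its values with the TR5 0 h HGF arrays (0.978 and 0.977) and array 9 (0.974) were close to each other. Among the TR7 arrays without HGF, array 6 correlated slightly more with that of 0 h (0.980) than with that of 6 h (0.976). This order goes against an exchange, so the correlations do not settle the labels either. No biological explanation was tested, and differences in culture or sampling between the experiments stay open, as does the unexplained mark bis in the label of array 6.

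Among the 1162 genes called for HGF averaged over 6, 12 and 24 h, 71.6% were lower, as were 494 of 539 with a replicate block by pair of experiment and time, 193 of 201 in TR5 alone and 14 of 16 in TR7 alone. With the spread of the arrays made equal by quantile normalization 66.6% of 1026 called genes were lower and 75.6% of the original calls were kept, and without arrays 6 and 10 the share was 62.1%, so neither a narrower spread with HGF nor these arrays explains the excess alone. In 100 splits of the arrays within each time, the real one included, the real split gave 1162 genes and the highest other 360. In the 32 splits that exchange arrays only within a pair of one experiment and time, the highest other gave 157. The real number of calls was above that of every other split tried. There were only 2 experiments, and arrays of one experiment may not be independent, so these splits do not exclude chance. For HGF at 0 h the 10 splits of the 6 arrays are too few for a share under 0.05, with 2 genes in the real split, the 1 split with as many, and 0 in the highest other. A lowering of transcripts by HGF remains a hypothesis, untested against an effect of the authors' normalization, which gave the arrays similar medians.

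By a direct test of the difference between HGF differences, 3 lists stood out after cisplatin against 0 h, with a median log2 interaction of -0.362 for G1/S genes, 0.375 for G2/M genes and -0.285 for MAPK/ERK genes. Arrays 6 and 10 are argued against as the whole cause, since without them the G1/S, G2/M and MAPK/ERK lists had camera adjusted p = 0.00203, 3.15e-05 and 0.00203 (adjusted p = 0.801 each with an estimated correlation), whereas correlated noise among the genes of a list may be the cause, since with an estimated correlation on all arrays their adjusted p was 0.403, 0.575 and 0.403. Gene by gene the real split called 0 genes, so that 100 of 100 splits had as many or more by construction and the splits decide nothing. The highest other of these splits called 402 genes, and exchanging all 6 pairs after cisplatin but not at 0 h, which adds the HGF differences instead of subtracting them, called 1226. With an estimated correlation 0 lists were called in each of 12 comparisons, so that test could hardly tell correlated noise from a shared change. A stronger HGF effect on these genes during cisplatin than before it is therefore open.

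Data outside the named genes also carried a signal. Of 3150 probe sets listed with several gene symbols or with none, 577 changed over 24 h without HGF, 306 higher and 271 lower, and 188 differed with HGF over 6, 12 and 24 h, 70 higher and 118 lower. In the same comparisons 3932 and 1162 of the 11963 tested genes were called, a larger share in each. The probe sets were not traced to genes.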

How the results depend on the processing

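The alternatives other than leaving out arrays 6 and 10 together, which was chosen after seeing the data, were planned. Among values that passed with or without the change of setting, the direction held except for 2 values of named genes and 1 of the fixed lists. The 2 lists written later, described in the last section, were not counted here. Of these, the small respiratory chain subunit list also reversed without arrays 6 and 10. Across named genes, with the DNA repair list counted among them, 10432 values stayed on their side of the threshold. A further 1636 were no longer past it and 50 came past it. Across the remaining lists these numbers were 1586, 112 and 29. For these and for the counts below the cause was not tested, apart from the fewer genes or arrays that some settings hold by construction. Signal over background was not analysed here, so its limit on low values is unknown.

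Reversed were CFLAR over 24 h without HGF (0.10) and PPP2CB over 24 h with HGF (0.17) when the probe sets of a gene were averaged, and the ribosomal protein list from 0 to 6 h with HGF without arrays 6 and 10 (adjusted p = 0.918).

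Counts of called genes that moved by over 1.5 times were these. With no replicate block, that is without the experiment in the fit, HGF at 0 h gave 0 genes, HGF at 6 h gave 1, HGF at 24 h gave 8, HGF averaged over 6, 12 and 24 h gave 755, 6 h without HGF gave 2 and 6 h with HGF gave 0, and the block changed no other count by as much. With the replicate block set by pair of experiment and time, the HGF average gave 539, and TR5 alone gave 201 and TR7 alone 16.

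With the TR5 arrays of each 0 h group averaged, HGF at 0 h gave 0, at 6 h 0 and at 24 h 3, the HGF average 727, the change without HGF 2 at 6 h, 838 at 12 h and 2518 at 24 h, and that with HGF 17 at 12 h and 1762 at 24 h. With a fold threshold of 1 on the log2 scale, HGF at 0 h gave 1, at 6 h 40 and on average 148, the change without HGF 1096 at 12 h and 1803 at 24 h, and that with HGF 1292 at 24 h.

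Without both arrays 6 and 10, HGF at 0 h gave 0, at 6 h 822, at 12 h 1, at 24 h 455 and on average 1979, the change without HGF gave 81 at 6 h and 3376 at 12 h, that with HGF 1487 at 6 h and 1478 at 12 h, and the F test 15. With trend and robust settings HGF at 0 h gave 7 and at 6 h 41. With genes below the median signal left out, HGF at 0 h gave 0 and at 6 h 33, the change without HGF 0 at 6 h, and that with HGF 0 at 6 h, 97 at 12 h and 1986 at 24 h.

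With the mean of all probe sets of a gene HGF at 0 h gave 0 and at 6 h 215. With only the groups compared in the fit, HGF at 0 h gave 1152, at 6 h 0, at 12 h 16, at 24 h 0 and on average 413, the change without HGF 237 at 6 h and 3409 at 12 h, and that with HGF 0 at 6 h and 0 at 12 h. With quantile normalization HGF at 0 h gave 5, 6 h without HGF 2 and 12 h with HGF 106.

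Leaving out 1 array at a time, which for most groups leaves a lone array assumed to vary like the others, gave 0 to 10 genes for HGF at 0 h, 0 to 926 at 6 h, 0 to 1 at 12 h, 0 to 805 at 24 h and 418 to 1891 on average. The change without HGF ranged from 0 to 49 at 6 h, 358 to 3240 at 12 h and 1288 to 4666 at 24 h, and that with HGF from 0 to 781 at 6 h, 0 to 701 at 12 h and 1764 to 4673 at 24 h. The difference between HGF differences ranged from 0 to 1 and the F test from 0 to 86.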

Other observations

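Both gene lists in this part were written after the named genes had been seen and before their own values were, and the readings of the small subunit test and of the last test were changed, and the values after quantile normalization and of the marker lists added, after values were seen.

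Several genes that fell most over 24 h of cisplatin without HGF, such as PTPRK, DPYD and FTO, are known to be very long, and a candidate explanation is that long transcription units fall more than others when cisplatin lesions block transcription. A list of large genes at common fragile sites and other very long genes, written without the genes already named, was lower than other genes over 24 h without HGF (camera adjusted p = 0.000427, adjusted p = 0.304 with an estimated correlation). Of 36 measured members 14 were called lower and 1 higher, 22 lay below and 14 above 0, with a median of -0.238, which was -0.404 in TR5 and -0.0179 in TR7. The hypothesis that HGF lessens this fall was tested on the HGF difference at 24 h, where 33 of 36 lay above 0 at a median of 0.283, 0.34 in TR5 and 0.192 in TR7 (camera adjusted p = 0.000625, adjusted p = 0.323 with an estimated correlation, 0 members called). After quantile normalization that median was 0.235 (camera adjusted p = 0.00326). Before that normalization the median lay at the 100 percentile of 10000 random lists matched for level. The median of the change without HGF lay at the 0.01 percentile. Such random lists do not carry a correlation among members, as real lists may. A rise of this size was also seen outside long genes, in lists not matched for level. Endothelial and leukocyte markers, which stand for other cell types, had medians of 0.28 and 0.24 for HGF at 24 h. After quantile normalization these were 0.236 and 0.167. Over 24 h with HGF 18 members lay below and 18 above 0, with a median of -0.014. The list was still lower than other genes there, with 11 members called lower and 0 higher (camera adjusted p = 0.0282, adjusted p = 0.653 with an estimated correlation). Members above 0 over 24 h without HGF also lay above 0 for HGF at 24 h, except DMD and GPC5. The 33 members above 0 therefore do not by themselves show a lessened fall. The change without HGF and the HGF difference both use the 24 h arrays without HGF, so a chance deviation of these arrays could move both values. Gene length itself was not measured, and the list rests on general knowledge of these genes.

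The opposite hypothesis, that short transcription units rise, stays undecided. A list of small respiratory chain subunit genes, 37 of which were measured, had a median of -0.00157 over 24 h without HGF (camera adjusted p = 0.423, 6 members lower and 2 higher), with 0.157 in TR5 and -0.242 in TR7. That median lay at the 96.4 percentile of random lists matched for level, and the medians at 12 h without and 24 h with HGF at the 98.4 and 99.7 percentiles (camera adjusted p = 0.519 and 0.45). A missed threshold had been set beforehand to count against the hypothesis, which was wrong, since it forbids nothing where the experiments go opposite ways.

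A weaker response to cisplatin with HGF might appear as HGF moving genes against their change without it. The 1482 genes that fell by 12 h without HGF had a median HGF difference at 24 h of 0.00781, which was -0.266 in TR5 and 0.234 in TR7, beside 0.0789 for all genes. The 720 genes that rose had a median of -0.0279, which was 0.0233 in TR5 and -0.0734 in TR7. Of these genes 50.7% and 52.5% were moved against their change, and across all genes the change at 12 h and the HGF difference at 24 h had r = -0.0178. The signs set beforehand for pooled medians were met, but the medians were near 0 and the experiments went opposite ways, so these data leave the question undecided.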
